A study of Mus musculus with 20 samples.

How the data were processed

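Transcript levels were measured in mouse pre-B cells on 20 Affymetrix Mouse 430 v2 arrays, 16 from 5 groups of cell lines and 4 from 2 groups of bone marrow cells. Per the labels, the arrays were read with the array maker's GeneChip Operating Software. The summary method, the background subtraction and the scaling between arrays are not given in the sources used here. The deposited values are log10 signals. This base was inferred from the values, since no label names it: on a base 10 scale they span the range of Affymetrix signals, and the spread between technical arrays at log10 values of 3 or more was 6.77% and 5.06% in the 2 pairs. The table held 44200 probe sets, and 14.7% of its cells were empty, between 6218 and 6640 per array. Empty cells were concentrated at low signal: 44.0% of cells were empty where the mean log10 signal of a probe set in the lines was below 0.5, and 0.0519% where it was 2 or more. Median signals were 26.8 to 27.7 in the lines and 46.9 to 47.8 in the bone marrow. Separate scaling of the 2 sets was inferred from these medians alone, and levels were compared only within each set. Arrays have no read depth, and the number of arrays per group limits the precision.

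The processing had been planned for linear or log2 values. The values turned out to be log10, so they were returned to signals and the plan for linear signals was used. Each signal was raised by a pseudocount, the 25th percentile of the signals in the set (6 in the lines, 11 in the bone marrow), and the sum was taken to log2. Empty cells were left empty. A probe set was kept for a set of arrays when at least 2 samples reached the median signal of their own array, which kept 21917 probe sets in the lines and 19520 in the bone marrow, of which 912 and 47 had an empty cell. The 2 technical arrays of each Artemis- and ATM-deficient line were averaged, with correlations across probe sets of 0.983 and 0.985 within the pairs, which left 14 line samples.

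Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend). All 5 groups of lines shared a fit with 9 residual and 3.06 prior degrees of freedom. The bone marrow groups had a fit of their own with 2 residual and 5.40 prior degrees of freedom. P values were two-sided and adjusted by Benjamini-Hochberg over the probe sets of each comparison, and a probe set was called at an adjusted p below 0.05. Changes are log2 differences with their standard error (SE), and levels are log2 values with their standard deviation (SD). Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

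Of the probe sets, 34294 named 1 gene, 916 named several and 8990 named none. A gene was represented by the probe set with the highest mean level, which gave 17944 genes, and other probe sets of a named gene are mentioned where they disagree. Probe sets naming several genes or none were tested and are not named. Positions in the genome were not used here. In each comparison the genes named are the 12 largest rises and 12 largest falls among called genes whose groups did not overlap, described by group, up to 4 called members of each gene list, and the targeted genes. Where a list had no called member, up to 2 members may be given as values. Genes named outside this rule are said to be chosen after their values were seen.

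The 21 gene lists were written from general knowledge before the data were examined, as were the comparisons, the tests and the naming rule. They cover NF-kB targets, p53 targets, lymphocyte homing and adhesion, the BCL-2 family and PIM kinases, B lineage transcription factors and pre-B receptor genes, non-homologous end joining and break signalling, homologous recombination, S phase genes, G2 and M phase genes, the interferon response, antigen presentation and costimulation, cytokines with TNF family ligands and receptors, immediate early genes, the unfolded protein response, and markers of mature B cells, plasma cells, early progenitors and pro-B cells, neutrophils and monocytes, erythroid cells, T and NK cells, and dendritic cells. Lists were tested with limma's camera over 1 probe set per gene, with a preset correlation of 0.01 and again with an estimated correlation, and adjusted over the lists within a comparison. There were 165 such tests over the 9 comparisons, because the lists of erythroid, T and NK, and dendritic cell markers had too few members in the lines. With the preset correlation 50 tests were called, and 5 of these held with an estimated correlation. Every adjusted p given for a list is from the preset correlation unless an estimated correlation is named.

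The calls were tested on simulated data with the sample numbers of 3 comparisons. With 3 against 3 lines, 39 of 100 probe sets changed by a log2 of 1 were called and 85 of 100 changed by 2, with 3.05% of calls false. For 3 against 2 lines the numbers were 37 of 99, 76 of 97 and 4.24%, and for 2 against 2 bone marrow samples 8 of 96, 81 of 99 and 6.32%. The simulated samples had independent errors and, for each probe set, the same spread in every group. The real line groups differed in spread (median SD 0.159 to 0.263), so the false shares may not hold for the real calls. Alternatives covered the pseudocount, the filter, the scaling, the variance model, array weights, the unit of testing, the samples in the fit, the handling of technical arrays, a fold threshold, the set correlation and each left-out sample. Alternatives chosen after seeing the data were the deposited log values without a pseudocount, empty cells set to a signal of 0, a G2 and M phase score as a covariate, and Artemis-deficient replicate 3 alone against the IkB-DN lines. Replicate numbers follow the order of the samples and pair nothing across groups. Transcripts of the Artemis gene were not analysed here.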

Results

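Transcript levels were measured in 7 groups of mouse pre-B cells, on 20 arrays. The 5 groups of lines were pre-B cells transformed by the v-abl oncogene and kept for 48 hours in 3 uM STI571 (imatinib), which inhibits the v-abl kinase; the arrest that follows is known to induce the RAG recombinase, which cuts DNA at antigen receptor genes. RAG-2-deficient lines (n = 3) cannot make these cuts and served as the control. Their titles contain the letters Bcl, which no other title does, and their source descriptions do not explain these letters. A further difference of the control lines is therefore not excluded. Wild type lines (n = 3) can cut and rejoin DNA, and Artemis-deficient lines (n = 3) can cut it but lack the nuclease that opens the hairpin ends, so that breaks stay unrepaired. In the other 2 groups of lines, Artemis deficiency was combined with loss of the break-signalling kinase ATM (n = 2, each on 2 arrays) or with a dominant negative IkB, which blocks NF-kB (n = 3, called IkB-DN lines here). Bone marrow pre-B cells carrying an IgH transgene were purified from Artemis-deficient mice (n = 2) and from RAG-1-deficient mice (n = 2), the control of that set. Correlations across probe sets between replicates, which are not independent measurements, were 0.910 to 0.935 in wild type, 0.934 to 0.946 in RAG-2-deficient, at least 0.926 in Artemis-deficient and 0.977 to 0.984 in IkB-DN lines. The IkB-DN range reaches that of technical arrays of the same sample (0.983 and 0.985). Whether the 3 IkB-DN samples are separate lines or cultures of the same line is not given in the sources used here. They were tested as separate lines, and if they are not, the p values of comparisons with them are too small. The 5 groups of lines share an estimate of the spread, so the p values of the other line comparisons may then be too small as well. The title of the series names gene activation by RAG breaks as its subject, and the comparisons ask which genes change with such breaks and which of these changes differ without ATM or with blocked NF-kB.

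The targeted genes were examined first as a check of the labels. On 1 of its 2 probe sets, Atm was 5.46 ± 0.03 (SD, n = 2) in Artemis- and ATM-deficient lines and 7.63 ± 0.02 (SD, n = 3) in RAG-2-deficient lines, and it fell by 2.18 ± 0.15 (SE, adjusted p = 2.61e-05). The same probe set was called lower in the Artemis-deficient lines (-0.87 ± 0.14, adjusted p = 0.0103) and the IkB-DN lines (-0.64 ± 0.14, adjusted p = 0.0137), in which Atm is not targeted. It lay between 7.41 and 7.46 in the 3 wild type lines. The title of the third of these contains the letters ATM, but its source is given as wild type and its Atm level is not that of the ATM-deficient lines, so it was kept as wild type with this doubt. The other Atm probe set differed by -0.70 ± 0.17 in the ATM-deficient lines and was not called (adjusted p = 0.0930). Rag2 transcripts were present in RAG-2-deficient lines at 7.03 ± 2.04 (SD, n = 3) and in Artemis-deficient lines at 8.29 ± 0.18 (SD, n = 3), with no call between them (1.26 ± 0.74). Rag1 was 11.05 ± 0.51 (SD, n = 3) in RAG-2-deficient lines. In bone marrow, where median signals were higher and levels are not comparable with the lines, it was 12.55 ± 0.23 (SD, n = 2) in RAG-1-deficient marrow cells, against 10.55 ± 0.38 (SD, n = 2) in Artemis-deficient ones. Which parts of these genes are deleted is not given in the sources used here, and a probe set outside the deleted part checks nothing. Nfkbia, which encodes IkB alpha, was higher in Artemis-deficient than in IkB-DN lines on all 5 of its probe sets, by 0.94 to 1.47, each of them called. Apart from these calls of Nfkbia and from lower Rag1 levels given with the comparisons concerned, the representative probe sets of Atm, Nfkbia, Rag1 and Rag2 were called in no comparison, with changes between -2.16 (Rag2, ATM-deficient against IkB-DN lines) and 1.87 (Rag2, IkB-DN against RAG-2-deficient lines).

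**Figure D1:**
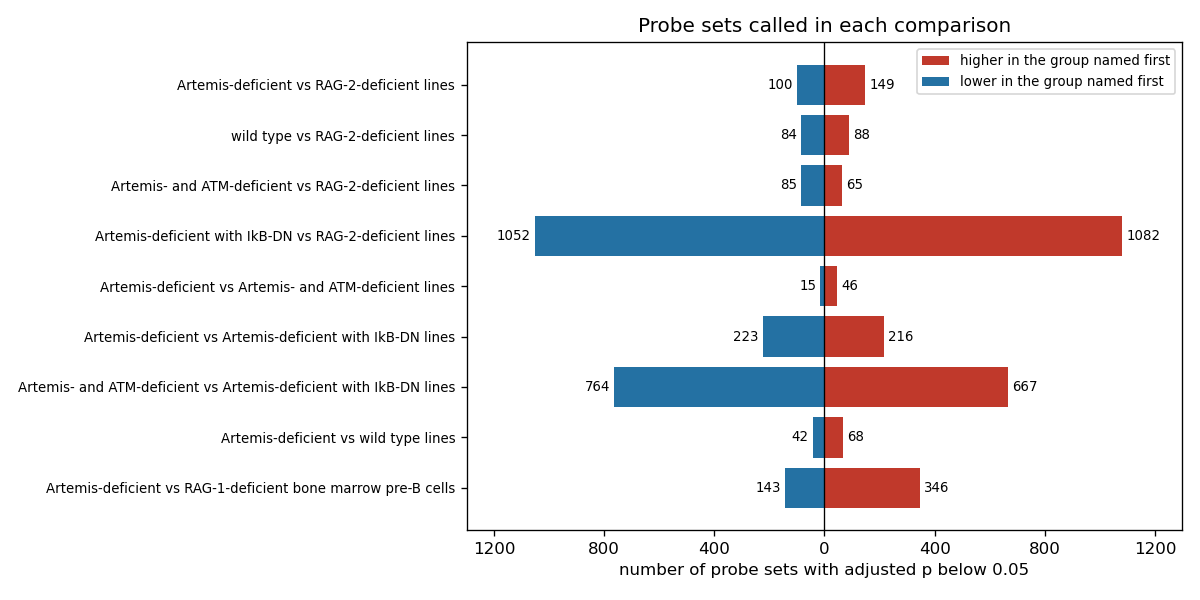
Bars show the number of probe sets called higher (right) or lower (left) in the group named first, in each of the 9 comparisons. Calls ran from 61 for Artemis-deficient against Artemis- and ATM-deficient lines to 2134 for IkB-DN against RAG-2-deficient lines.

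The comparison of Artemis-deficient with RAG-2-deficient lines asks what unrepaired RAG breaks change. In the Artemis-deficient lines genes of the NF-kB pathway rose. Nfkbie, which encodes the NF-kB inhibitor IkB epsilon, rose by 2.04 ± 0.17 (log2, SE, n = 3 and 3, adjusted p = 0.000115), and Tnfaip3, the A20 brake on NF-kB signalling, rose by 1.675 ± 0.25 (adjusted p = 0.00768). The NF-kB subunit gene Relb rose by 1.10 ± 0.18, the adhesion molecule Icam1 by 0.74 ± 0.14, and Pim2, a survival kinase, by 2.76 ± 0.55. With Nfkb2 (0.78 ± 0.17), chosen after its values were seen, and with a larger change on another probe set (3.17, adjusted p = 6.77e-05), these made 6 of the 22 tested NF-kB targets that rose, and none fell; 11 rose when adjusted over the list alone. The list was higher as a set (median change 0.52, adjusted p = 1.32e-08, and adjusted p = 0.0289 with an estimated correlation). Nfkbid, another IkB family member, rose by 2.28 ± 0.36 (adjusted p = 0.00979).

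Genes of lymphocyte homing and adhesion rose in the same lines, 4 of 19 (5 when adjusted over the list alone): Swap70, which acts on the actin cytoskeleton (1.39 ± 0.21), Icam1, the activation marker Cd69 (1.63 ± 0.35) and the chemokine receptor Cxcr4 (0.89 ± 0.19). The adjusted p of the list was 0.0426, and adjusted p = 0.186 with an estimated correlation, and the groups overlapped in its mean level, with 0.07 in Artemis-deficient replicate 2 and 0.09 in RAG-2-deficient replicate 1. Among cytokine and TNF family genes only Il12a, a subunit of interleukin 12, rose of 18 tested (2.23 ± 0.33, adjusted p = 0.00683), with 3 rises when adjusted over the list alone. That list had an adjusted p of 0.0318, and adjusted p = 0.186 with an estimated correlation. The immediate early transcription factor genes Junb (0.93 ± 0.17) and Jund (0.65 ± 0.12) rose among 12 on their list; adjusted over the list alone, 5 rose and 2 fell (adjusted p = 0.00557, and adjusted p = 0.382 with an estimated correlation). RAG-2-deficient replicate 1 stood apart on this list: the mean level, relative to the mean of all line samples, was -0.84, 0.02 and -0.10 in the RAG-2-deficient and 0.19, 0.08 and -0.05 in the Artemis-deficient lines. In antigen presentation the class I gene H2-K1 rose by 0.39 ± 0.06, as the only call of 13; adjusted over the list alone, 3 rose and 1 fell (adjusted p = 0.0173, and adjusted p = 0.276 with an estimated correlation). Artemis-deficient replicate 3 stood apart on that list (1.07, against 0.27 and 0.14), and RAG-2-deficient replicate 1 (0.56) lay above the other 2 Artemis-deficient lines. Of the 25 p53 targets limma called 0 at an adjusted p below 0.05 and 4 at an unadjusted p below 0.05, among them Ei24 (0.82 ± 0.31, adjusted p = 0.263) and Dcxr (1.30 ± 0.52, adjusted p = 0.289). The p53 list was nonetheless higher as a set with the preset correlation, with 19 of 25 changes positive (median 0.59, adjusted p = 0.0173), but not with an estimated correlation (adjusted p = 0.612). The rise was not in every line: the mean p53 target level, relative to the mean of all line samples, was 1.07 and 1.03 in Artemis-deficient replicates 1 and 2 but -0.30 in replicate 3, and -0.35, -0.57 and 0.59 in the RAG-2-deficient lines.

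Members called from other lists were the break-signalling kinase Atr (0.92 ± 0.20, 1 of 22), the complement regulator Cd55 (1.63 ± 0.30, 1 of 6 mature B cell markers), the receptor Notch1 (1.30 ± 0.26, 1 of 9 progenitor markers) and the replication helicase subunit Mcm6, which fell by 1.40 ± 0.28 (1 of 21 S phase genes). The S phase list had an adjusted p of 0.0426, and adjusted p = 0.722 with an estimated correlation, and RAG-2-deficient replicate 3 (-0.45) lay among the Artemis-deficient lines (-0.51, -0.29 and -0.35). In the lists of the BCL-2 family, end joining, mature B cells and progenitors the set test was not called (adjusted p between 0.0882 and 0.673). limma called 0 genes of 8 in homologous recombination, 31 in the B lineage, 23 in G2 and M phase, 14 in the interferon response, 15 in the unfolded protein response and 7 among plasma cell markers; at an unadjusted p below 0.05 these lists held 1, 4, 0, 5, 4 and 1 genes. The markers of neutrophils and monocytes (6 genes), erythroid cells (2), T and NK cells (3) and dendritic cells (2) had no call either, with 1, 0, 3 and 0 genes at an unadjusted p below 0.05.

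The largest rises lay outside the lists. Akr1c13, an aldo-keto reductase, rose by 4.62 ± 0.35 (adjusted p = 5.48e-05) and Bloc1s2, a subunit of a lysosome-related organelle complex, by 2.84 ± 0.25 (adjusted p = 0.000151). Akr1c13 was also called higher than in RAG-2-deficient lines in wild type (4.20), Artemis- and ATM-deficient (4.17) and IkB-DN lines (4.47), so its difference followed the RAG-2-deficient group against each of the other line groups. Txndc15 (2.97 ± 0.56), 3830406C13Rik (2.79 ± 0.57), Zfp982 (2.88 ± 0.43), Fv1 (2.43 ± 0.31) and Abca8b (2.25 ± 0.47) rose as well. The protease gene Ctse (5.72 ± 1.23) and Xaf1 (2.69 ± 0.36) were called higher, but another probe set of each gene went the other way, by -1.51 and -2.13. Cpeb2, which binds mRNA, fell by 3.92 ± 0.73, Gfod1 by 2.82 ± 0.44, the cytokine receptor gene Lifr by 2.71 ± 0.40, the RNA-binding Pcbp4 by 1.53 ± 0.27 and Lancl1 by 1.51 ± 0.19. The other falls among the 12 largest were those of 2610507I01Rik, Slc4a8, Pyurf, Prr18, 4933404O12Rik, 4930594M22Rik and 6530402F18Rik (-2.39 to -1.51, SE 0.25 to 0.48). In all, 249 of 21740 probe sets were called, 149 higher and 100 lower, or 105 of 9762 genes. The count was 93 without RAG-2-deficient replicate 1, 160 without replicate 2, 148 without replicate 3 and 146 without Artemis-deficient replicate 2. Of 44 called genes, those given for this comparison with Ccnd1, Map3k8, Cyba, Sdhaf1 and Slc20a1, 17 stayed called whichever sample was left out: Akr1c13, Nfkbie, Bloc1s2, Tnfaip3, Il12a, Swap70, H2-K1, Xaf1, Zfp982, Gfod1, Lifr, Lancl1, Ccnd1, Cyba, Sdhaf1, Slc20a1 and 4933404O12Rik.

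**Figure D2:**
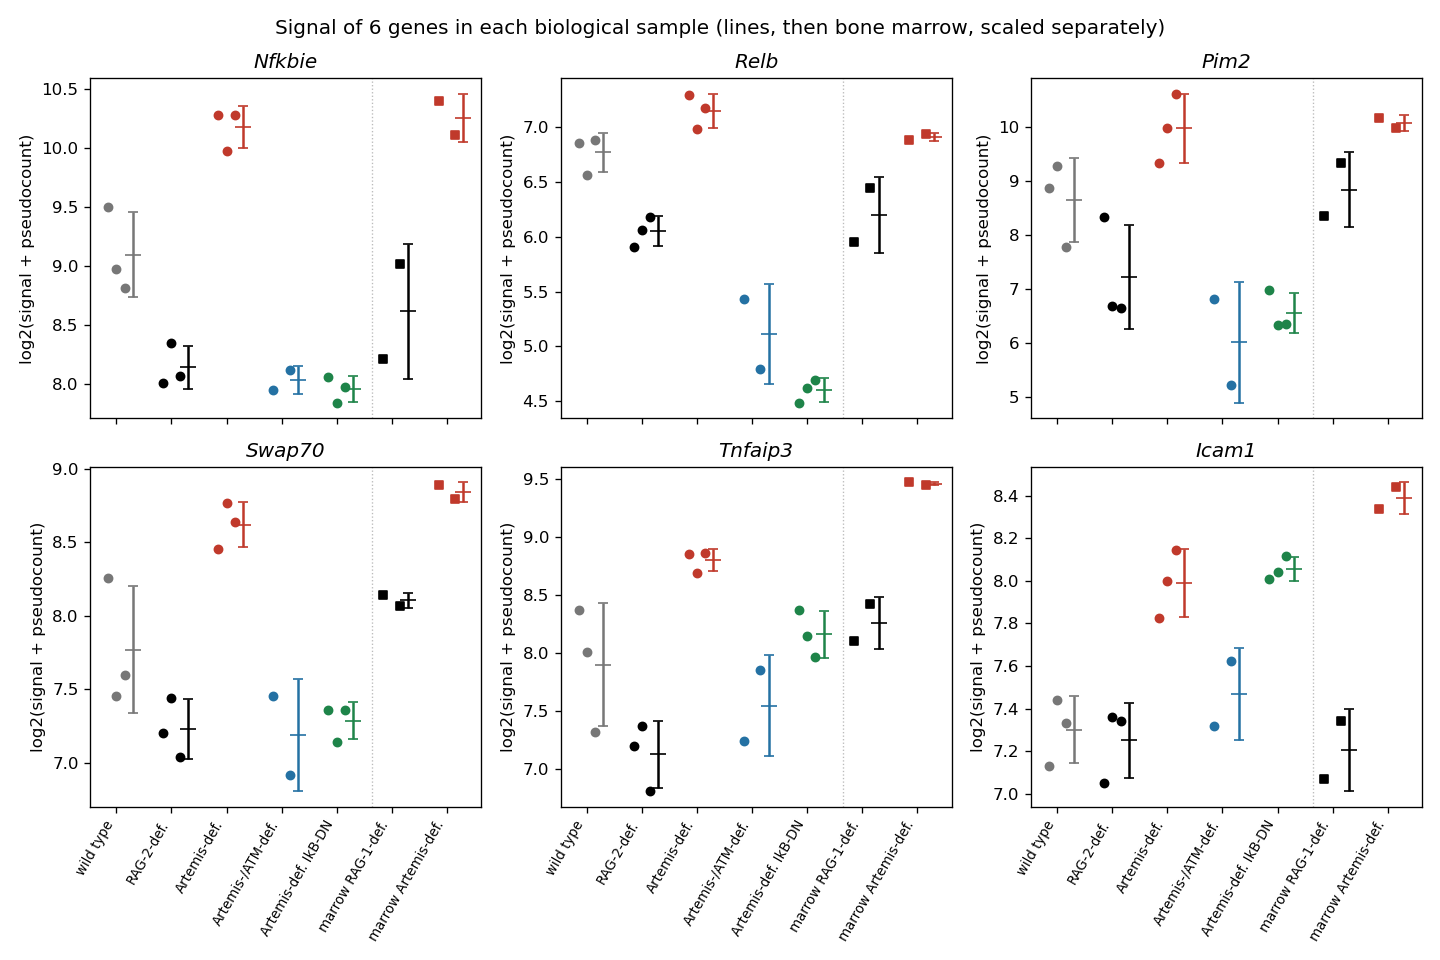
Points show log2(signal + pseudocount) of 6 genes in each biological sample, with the mean and SD of each group beside them; circles are lines and squares bone marrow cells, whose levels are not comparable with those of the lines. Nfkbie lies between 9.97 and 10.28 in the 3 Artemis-deficient lines and between 7.84 and 8.35 in the RAG-2-deficient, Artemis- and ATM-deficient and IkB-DN lines.

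Wild type lines, in which breaks can be joined, were compared with RAG-2-deficient lines for the effect of breaks that are repaired. Nfkbie rose by 0.96 ± 0.17 (SE, n = 3 and 3, adjusted p = 0.0287), the only call among 22 NF-kB targets, with 2 rises and 1 fall when adjusted over the list alone; the list as a set was not called (adjusted p = 0.278). Akr1c13 (4.20 ± 0.35), Bloc1s2 (2.21 ± 0.25), Txndc15 (3.40 ± 0.56), Fggy (2.78 ± 0.41), the cyclin gene Ccnd1 (2.12 ± 0.26) and the complement receptor Cr2 (2.54 ± 0.44), 1 of 6 mature B cell markers, rose. Jund (0.58 ± 0.12) was the call among 12 immediate early genes and Notch1 (1.38 ± 0.26) the call among 9 progenitor markers. The immediate early list had an adjusted p of 0.0104, and adjusted p = 0.744 with an estimated correlation; its mean level was 0.32, -0.06 and 0.35 in the wild type lines and -0.84, 0.02 and -0.10 in the RAG-2-deficient lines, of which replicate 1 stood apart. A kappa light chain variable gene, Igkv6-14, rose by 2.02 ± 0.36. The TNF receptor family gene Tnfrsf19 fell by 3.23 ± 0.31 (adjusted p = 0.000388), the NK cell receptor Klrd1 by 4.08 ± 0.78 and Bst1 by 1.81 ± 0.30. Among the 12 largest rises were also Bend4, Cryz, Flrt1 and Pfkm (2.04 to 2.27, SE 0.32 to 0.42), and among the 12 largest falls Tmem163, Spo11, Gpr19, Arhgef3, B3gnt2, Cd244a, Plin2 and Oxr1 (-2.67 to -1.36, SE 0.22 to 0.53), with n = 2 and 3 for Tmem163.

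S phase genes were higher in wild type as a set, with 20 of 21 changes positive and a median of 0.40 (adjusted p = 0.0104), but not with an estimated correlation (adjusted p = 0.744). Wild type replicate 1 stood apart: the mean level of the list, relative to all line samples, was 1.428, 0.34 and -0.33 in wild type replicates 1 to 3 and 0.11, 0.22 and -0.45 in the RAG-2-deficient lines. limma called 0 of them and 5 at an unadjusted p below 0.05, among them Tk1 (2.01 ± 0.51, adjusted p = 0.142) and Prim1 (1.38 ± 0.39, adjusted p = 0.156). The homing list had 0 calls of 19, with Icam2 at -0.80 ± 0.18 (adjusted p = 0.0722) and Cd69 at 1.49 ± 0.35 (adjusted p = 0.0784). Xist, expressed from the inactive X chromosome, rose by 6.997 ± 1.443 and the Y-linked Uty fell by 3.10 ± 0.58. Xist lay between 11.65 and 12.09 in the 3 wild type lines, 11.41 and 11.71 in the ATM-deficient lines and at 11.90 in Artemis-deficient replicate 1, and between 4.09 and 5.64 in the other lines. The line groups therefore differ in sex-linked transcripts. Of 21731 probe sets, 172 were called, 88 higher and 84 lower. The count was 76 without wild type replicate 1, 302 without replicate 2, 109 without replicate 3, 82 without RAG-2-deficient replicate 1 and 69 without RAG-2-deficient replicate 3. With only the 2 compared groups in the fit it was 29, of which 10 were higher and 19 lower. Of 27 called genes named, Akr1c13, Bloc1s2, Tnfrsf19, Ccnd1 and Fggy stayed called whichever sample was left out.

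The response of the Artemis-deficient lines overlapped that of wild type. Of 148 probe sets called higher in Artemis-deficient than in RAG-2-deficient lines and tested in both, 39 were also called higher in wild type, and 21 of 100 lower ones were called lower. Both comparisons share the RAG-2-deficient samples, which alone gives a covariance of changes of 0.0476 in simulated data, and the measured covariance was 0.123. As correlations the values were much closer, 0.501 in simulated data and 0.546 measured. The measured changes thus varied more than the simulated ones, and the covariances are not on a like scale. The overlap was not particular to wild type: 35 higher and 31 lower probe sets were shared with the ATM-deficient lines (covariance 0.136) and 96 and 76 with the IkB-DN lines (0.192), all against the same RAG-2-deficient samples. A direct comparison of Artemis-deficient with wild type lines tests whether unrepaired breaks change more than joined ones. Nfkbie was higher in the Artemis-deficient lines by 1.08 ± 0.17 (SE, n = 3 and 3, adjusted p = 0.0199). It was the only call of 23 NF-kB targets, with 8 rises when adjusted over the list alone, and the list was higher as a set (median 0.51, adjusted p = 5.34e-08, and adjusted p = 0.0331 with an estimated correlation). Icam2 (0.98 ± 0.18) and Coro1a (1.13 ± 0.22), which acts on actin, rose among 19 homing genes; adjusted over the list alone, 6 rose and 1 fell (adjusted p = 0.00207, and adjusted p = 0.0360 with an estimated correlation). No cytokine gene of 18 was called, with 3 rises when adjusted over the list alone; Ltb (2.86 ± 0.72, adjusted p = 0.112) and Il12a (1.30 ± 0.33, adjusted p = 0.113) had the smallest p. The cytokine list was higher as a set (adjusted p = 0.000810, and adjusted p = 0.0331 with an estimated correlation). Other lists were higher only with the preset correlation. These were p53 targets (24 of 26 positive, adjusted p = 0.000754, and adjusted p = 0.429 with an estimated correlation), antigen presentation (12 of 13 positive, adjusted p = 0.000492, and adjusted p = 0.0919 with an estimated correlation) and B lineage genes (23 of 31 positive, adjusted p = 0.0224, and adjusted p = 0.136 with an estimated correlation). In the first 2 of these limma called 0 genes, with 4 and 3 at an unadjusted p below 0.05, and Artemis-deficient replicate 3 stood apart, lowest of its group for p53 targets (-0.30) and highest for antigen presentation (1.07, against 0.27 and 0.14).

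In the same comparison 20 of 21 S phase genes had negative changes (median -0.75, adjusted p = 2.40e-07, and adjusted p = 0.288 with an estimated correlation). The mean S phase level was -0.51, -0.29 and -0.35 in the Artemis-deficient lines, and wild type replicate 3 (-0.33) lay among them while replicate 1 (1.428) stood apart. Mcm6 fell by 1.56 ± 0.28, the call of the list, with 4 falls when adjusted over the list alone, and the clamp loader subunit Rfc3 by 1.60 ± 0.20 (adjusted p = 0.00750). All 23 G2 and M phase genes were negative, with 0 called by limma and 1 at an unadjusted p below 0.05 (median -1.10, adjusted p = 0.000450, and adjusted p = 0.568 with an estimated correlation). Their mean level was 2.69, 0.73 and -1.27 in the wild type lines and 0.27, -0.08 and -1.32 in the Artemis-deficient lines. Tnfrsf19 (2.83 ± 0.31), Cd244a (2.68 ± 0.28), Sh2d5 (3.27 ± 0.50), the lymphocyte surface gene Cd52 (1.73 ± 0.29), Cd72 (1.05 ± 0.17, the 1 call of 31 B lineage genes) and Cd55 (1.675 ± 0.30) rose. Osr2 fell by 4.07 ± 0.61, the transcriptional cofactor gene Cited2 by 2.44 ± 0.25, Lifr by 2.40 ± 0.40, and the kappa variable genes Igkv6-20 and Igkv6-14 by 2.87 ± 0.55 and 2.35 ± 0.36. The remaining genes among the 12 largest rises were Igfbp4, Zfp982, Tmod4, Kif17, Xaf1, Ehd3, Rnf144a and Vangl1 (1.82 to 3.02, SE 0.30 to 0.57), with another probe set of Xaf1 at -1.33. Those among the 12 largest falls were Bend4, Kif18a, 2010109A12Rik, 4933404O12Rik, Pcbp4 and Flrt1 (-2.54 to -1.69, SE 0.25 to 0.42). Of 21787 probe sets, 110 were called, 68 higher and 42 lower. The count was 45 without Artemis-deficient replicate 2 and 180 without wild type replicate 3. It was far lower still with only the 2 compared groups in the fit, as given with the processing settings below. Of 30 called genes named, Tnfrsf19, Cd244a, Osr2, Cited2, Rfc3, Tmod4 and 4933404O12Rik stayed called whichever sample was left out.

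Artemis- and ATM-deficient lines were compared with RAG-2-deficient lines for the effect of unrepaired breaks without ATM. limma called 0 of 22 NF-kB targets in these lines, and 3 were lower at an unadjusted p below 0.05, among them Relb (-0.94 ± 0.20, SE, n = 2 and 3, adjusted p = 0.0619) and Nfkbib (-0.53 ± 0.17, adjusted p = 0.219). The list as a set was not called (median -0.10, adjusted p = 0.457). Junb rose by 1.04 ± 0.19 as the only call among 12 immediate early genes and in all 21 lists. Akr1c13 (4.17 ± 0.40, adjusted p = 0.000380), Bloc1s2 (2.71 ± 0.28), Xaf1 (3.51 ± 0.40, with another probe set at -2.12) and Tmod4 (2.49 ± 0.34) rose. The ribonuclease genes Rnase4 and Ang fell (-3.81 ± 0.54 and -3.58 ± 0.68), as did Gfod1 (-2.99 ± 0.49) and Tnfrsf19 (-2.35 ± 0.34). Further genes among the 12 largest rises were Acpp, Adat2, Abi2, Rab32, C730049O14Rik, Rnf125, Dixdc1 and Shox2 (2.33 to 3.28, SE 0.36 to 0.53), with n = 2 and 2 for Acpp and Shox2. Further genes among the 12 largest falls were Snx10, Zfp760, 2610507I01Rik, Scpep1, Dnah1, Zbtb42, Plekhb2 and 4933404O12Rik (-3.37 to -2.08, SE 0.28 to 0.53). All 23 G2 and M phase genes had positive changes (median 1.09, adjusted p = 0.00254, and adjusted p = 0.901 with an estimated correlation), and 0 of them were called or had an unadjusted p below 0.05; Kif20a was at 1.55 ± 0.80 and Bub1b at 1.42 ± 0.72. The mean level of the list was 0.98 and 1.10 in the ATM-deficient lines and 0.18, 1.06 and -1.20 in the RAG-2-deficient lines. Rag1 was at -1.15 ± 0.42 (adjusted p = 0.289). Of 21655 probe sets, 150 were called, 65 higher and 85 lower. The count was 46 without Artemis- and ATM-deficient replicate 2 and 54, 92 and 95 without RAG-2-deficient replicate 1, 2 and 3; Akr1c13, Bloc1s2, Xaf1 and 4933404O12Rik, of 25 called genes named, stayed called whichever sample was left out.

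Artemis-deficient lines were then compared directly with Artemis- and ATM-deficient lines, which tests whether changes with unrepaired breaks differ without ATM. NF-kB targets were higher where ATM was present. Ltb, which encodes lymphotoxin beta, was higher by 5.05 ± 0.81 (SE, n = 3 and 2, adjusted p = 0.0262), Pim2 by 3.97 ± 0.62 (adjusted p = 0.0235), Nfkbie by 2.15 ± 0.19 (adjusted p = 0.000352) and Relb by 2.04 ± 0.20 (adjusted p = 0.000834). These were 4 of 23 members; adjusted over the list alone, 14 rose and 1 fell. The list was higher as a set (median 0.70, adjusted p = 5.87e-11, and adjusted p = 0.0127 with an estimated correlation). The homing genes Swap70 (1.431 ± 0.24) and Cd44, a hyaluronan receptor (4.61 ± 0.80), rose of 19, with 4 rises when adjusted over the list alone; the list was not called (adjusted p = 0.0984). Shisa5 (2.55 ± 0.34), known as a p53 target outside the lists used here, Zfp760 (4.13 ± 0.49), the peptidase Pepd (4.06 ± 0.42), Zbtb42 (2.98 ± 0.42), the beta-oxidation enzyme Decr1 (2.25 ± 0.36), Pvr (2.38 ± 0.44) and Tmlhe (3.38 ± 0.58) rose as well. The antiviral deaminase gene Apobec3 fell by 2.01 ± 0.25, Cited2 by 1.70 ± 0.28, Shox2 by 2.69 ± 0.42, the signalling inhibitor Socs2 by 0.94 ± 0.17 and H2-M3 by 1.34 ± 0.24. The chromatin remodeller Chd1 was called lower (-0.75 ± 0.14), with another probe set at 0.41.

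The p53 list was higher in the Artemis-deficient lines as a set (median 0.87, adjusted p = 0.0135), but not with an estimated correlation (adjusted p = 0.472). Its mean level was 1.07 and 1.03 in Artemis-deficient replicates 1 and 2 but -0.30 in replicate 3, and -0.66 and 0.38 in the ATM-deficient lines. limma called 0 of its 26 genes and 5 at an unadjusted p below 0.05; Pidd1 was at 3.08 ± 0.42 (n = 2 and 2, adjusted p = 0.0519) and Sesn2 at 1.81 ± 0.44 (adjusted p = 0.148). Of 12 immediate early genes limma called 0, and 4 were higher and 1 lower at an unadjusted p below 0.05, with Jun at 2.29 ± 0.48 (adjusted p = 0.0900) and the heat shock gene Hspa1b at 1.91 ± 0.40 (adjusted p = 0.0847). That list was higher as a set, with 4 rises when adjusted over the list alone (adjusted p = 0.03, and adjusted p = 0.472 with an estimated correlation). The BCL-2 family and PIM kinases, with Pim2 as the 1 call of 16, were higher as well (adjusted p = 0.03, and adjusted p = 0.202 with an estimated correlation). So was antigen presentation, with 0 calls of 13 and 3 higher and 2 lower at an unadjusted p below 0.05 (adjusted p = 0.0158, and adjusted p = 0.285 with an estimated correlation), and Artemis-deficient replicate 3 stood apart on it (1.07, against 0.27 and 0.14). Of 23 G2 and M phase genes 22 had negative changes (median -1.50, adjusted p = 8.62e-07, and adjusted p = 0.472 with an estimated correlation), with 0 calls and 0 at an unadjusted p below 0.05; Kif20a was at -1.71 ± 0.80 and Plk1 at -1.30 ± 0.61. Their mean level was 0.27, -0.08 and -1.32 in the Artemis-deficient and 0.98 and 1.10 in the ATM-deficient lines. Of 21703 probe sets, 61 were called, 46 higher and 15 lower, and 29 without Artemis- and ATM-deficient replicate 2. Of 22 called genes, those named here with Cyba, Sdhaf1 and Slc20a1, 6 stayed called whichever sample was left out: Nfkbie, Relb, Zfp760, Pepd, Apobec3 and Sdhaf1.

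IkB-DN lines were compared with RAG-2-deficient lines for the effect of unrepaired breaks with blocked NF-kB. Relb fell by 1.45 ± 0.18 (SE, n = 3 and 3, adjusted p = 0.000991) and the survival gene Bcl2l1 by 0.55 ± 0.14, with Nfkbib (-0.60 ± 0.15), chosen after its values were seen, while Icam1 rose by 0.80 ± 0.14 and Tnfaip3 by 1.03 ± 0.25. These 2 rises and 3 falls among 21 NF-kB targets, or 3 and 4 when adjusted over the list alone, left the list as a set uncalled (median 0.08, adjusted p = 0.956). Markers of neutrophils and monocytes rose, 4 of 7 both over all and when adjusted over the list alone: the integrin Itgam (4.33 ± 0.76), the lysozymes Lyz1 (3.99 ± 0.36, n = 3 and 2) and Lyz2 (3.22 ± 0.44) and the protease Elane (0.95 ± 0.25). That list had an adjusted p of 0.0164, and adjusted p = 0.378 with an estimated correlation. The immediate early genes Jun (2.73 ± 0.43), Ier2 (0.65 ± 0.16) and Jund (0.44 ± 0.12) rose of 12, or 5 when adjusted over the list alone (adjusted p = 0.0164, and adjusted p = 0.664 with an estimated correlation). The mean level of this list was 0.37, 0.24 and 0.18 in the IkB-DN lines and -0.84, 0.02 and -0.10 in the RAG-2-deficient lines, of which replicate 1 stood apart. The cytokine genes Tnfsf10, the death ligand TRAIL (2.49 ± 0.21, adjusted p = 8.97e-05), and Il18 (1.75 ± 0.32) rose of 16; adjusted over the list alone, 3 rose and 1 fell (adjusted p = 0.0374, and adjusted p = 0.362 with an estimated correlation).

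The plasma cell regulators Prdm1 (-4.17 ± 0.83) and Irf4 (-0.90 ± 0.26) fell in the IkB-DN lines, 2 of 7 plasma cell markers. Of 31 B lineage genes the surrogate light chain gene Igll1 rose (2.02 ± 0.48), and the transcription factor Foxo1 (-0.48 ± 0.12), Cd24a (-0.27 ± 0.07) and Irf4 fell. Herpud1 (-0.61 ± 0.07) and Hsp90b1 (-0.87 ± 0.20), both of the endoplasmic reticulum stress response, fell of 15. The repair genes Prkdc (0.77 ± 0.18), Parp1 (1.49 ± 0.39) and Poll (0.66 ± 0.17) were among 4 rises of 21 end joining genes, and Rad50 fell by 1.26 ± 0.34. Of 24 p53 targets Ddb2 rose by 1.20 ± 0.26, and Gadd45a, Rrm2b and Ercc5 fell by 2.09 ± 0.44, 1.15 ± 0.26 and 1.73 ± 0.43. None of these 5 lists was called as a set (adjusted p between 0.213 and 0.886). Of 19 homing genes Cd47 (1.16 ± 0.20) and Coro1a (0.86 ± 0.22) rose with Icam1, and the selectin ligand gene Selplg fell (-1.20 ± 0.24). Palb2 (0.82 ± 0.20) rose as 1 of 8 homologous recombination genes and Fcrl1 (3.48 ± 0.91) as 1 of 6 mature B cell markers; the sets were not called (adjusted p of 0.651, 0.886 and 0.450). All 23 G2 and M phase genes had negative changes (median -1.04, adjusted p = 0.0183, and adjusted p = 0.756 with an estimated correlation), with 0 called by limma and 0 at an unadjusted p below 0.05. Their mean level was -0.68, -1.32 and -1.14 in the IkB-DN lines and 0.18, 1.06 and -1.20 in the RAG-2-deficient lines. The actin-associated genes Sptbn1 (-6.95 ± 1.35), Pfn2 (-5.52 ± 0.69) and the mRNA-binding Cpeb2 (-5.44 ± 0.73) fell, and Retreg1 and Akr1c13 rose by 5.07 ± 0.82 and 4.47 ± 0.35. Others among the 12 largest rises were Ctse, 1700048O20Rik, Osbpl3, Plod2, 1500002F19Rik, Zfp182, Plch1 and Rnf130 (3.93 to 6.20, SE 0.66 to 1.23), with another probe set of Ctse at -1.15. Others among the 12 largest falls were Slc15a2, Tceal9, Sspn, Trim34a, Camk4, Acp5, Cacna1e and Trim5 (-6.49 to -4.22, SE 0.40 to 1.76), with n = 2 and 3 for Slc15a2, Tceal9, Sspn and Acp5. Another probe set of Trim34a was called the other way (0.91, adjusted p = 0.0447). Of 21664 probe sets, 2134 were called, 1082 higher and 1052 lower. The count was 941, 840 and 1131 without IkB-DN replicate 1, 2 and 3, and 1243 and 1352 without RAG-2-deficient replicate 1 and 3. Of 55 called genes named, 21 stayed called whichever sample was left out: Itgam, Lyz2, Tnfsf10, Il18, Jun, Relb, Icam1, Prdm1, Herpud1, Sptbn1, Pfn2, Cpeb2, Akr1c13, Retreg1, Ctse, 1700048O20Rik, Osbpl3, 1500002F19Rik, Trim5, Cd47 and Selplg.

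The direct comparison of Artemis-deficient with IkB-DN lines tests whether changes with unrepaired breaks differ when NF-kB is blocked. Relb was higher in the Artemis-deficient lines by 2.55 ± 0.18 (SE, n = 3 and 3, adjusted p = 0.000120), Nfkbie by 2.22 ± 0.17 (adjusted p = 0.000120), Pim2 by 3.42 ± 0.55 and Nfkbia by 1.17 ± 0.18. Birc3 (1.14 ± 0.20), an inhibitor of apoptosis, and Nfkb2 (0.82 ± 0.17), both chosen after their values were seen, complete the 6 of 22 NF-kB targets that were higher; adjusted over the list alone, 13 rose and 2 fell. The list was higher as a set (median 0.54, adjusted p = 9.59e-06), but not with an estimated correlation (adjusted p = 0.1). Swap70 (1.33 ± 0.21) and Cd69 (1.97 ± 0.35) rose and the integrin-associated Cd47 (-0.97 ± 0.20) fell of 19 homing genes. H2-K1 (0.38 ± 0.06), Il12a (1.76 ± 0.33) and Herpud1 (0.41 ± 0.07) rose as well. H2-K1 was the 1 call of 12 antigen presentation genes, with 4 rises when adjusted over the list alone (adjusted p = 0.00488, and adjusted p = 0.199 with an estimated correlation; replicate 3 of the Artemis-deficient lines again stood apart at 1.07), and Pim2 that of 16 genes of the BCL-2 family and PIM kinases (adjusted p = 0.0169, and adjusted p = 0.131 with an estimated correlation). S phase genes were lower as a set, with 0 of 20 called by limma and 3 lower at an unadjusted p below 0.05 (adjusted p = 0.0357, and adjusted p = 0.733 with an estimated correlation). Tnfsf10 fell by 1.92 ± 0.21 and Il18 by 1.666 ± 0.32. Of 25 p53 targets Pidd1 rose (3.54 ± 0.42, n = 2 and 2) and Ddb2 fell (-1.12 ± 0.26); adjusted over the list alone, 10 rose and 1 fell (median 1.17, adjusted p = 9.18e-05, and adjusted p = 0.570 with an estimated correlation). The mean p53 target level of Artemis-deficient replicate 3 (-0.30) was close to that of the IkB-DN lines (-0.49, -0.50 and -0.29), and replicates 1 and 2 (1.07 and 1.03) stood apart.

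Markers of other blood cells also separated these lines. Lyz2 was lower in the Artemis-deficient than in the IkB-DN lines (-3.40 ± 0.44, adjusted p = 0.00490), 1 of 6 neutrophil and monocyte markers, with 5 falls when adjusted over the list alone (adjusted p = 0.00945, and adjusted p = 0.199 with an estimated correlation). The myeloid receptor Trem1 (-3.11 ± 0.37), Crisp3 (-3.96 ± 0.56), the homeobox gene Hoxb6 (-3.27 ± 0.41) and the NK cell receptor Klrd1 (-3.97 ± 0.78) fell, and Ly6d (3.63 ± 0.81), Gadd45g (3.20 ± 0.66), Pfn2 (4.67 ± 0.69) and Tceal9 (4.79 ± 0.65, n = 2 and 2) rose. Also among the 12 largest rises were Adamts7, Nuak1, Eng, Trim5, Add3 and Vsir (2.59 to 4.14, SE 0.33 to 0.86), with another probe set of Add3 at -0.03. Also among the 12 largest falls were Uaca, Garem1, Emp1, Igsf5, Rgs8, Cabp4 and Paqr7 (-4.47 to -2.68, SE 0.34 to 0.96). For Adamts7, Trim5, Uaca, Igsf5 and Paqr7 n was 2 and 3. Artemis-deficient replicate 3 correlated with the IkB-DN lines at 0.944 to 0.949 across probe sets, and replicates 1 and 2 at 0.905 to 0.929. Of 21732 probe sets, 439 were called, 216 higher and 223 lower. The count was 79, 242 and 1065 without Artemis-deficient replicate 1, 2 and 3, and 99, 59 and 115 without IkB-DN replicate 1, 2 and 3. Of 41 called genes, those named here with Cyba, Sdhaf1 and Slc20a1, 13 stayed called whichever sample was left out: Relb, Nfkbie, Tnfsf10, Lyz2, Pfn2, Crisp3, Trem1, Hoxb6, Cyba, Sdhaf1, Slc20a1, Add3 and Cabp4.

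Higher levels in Artemis-deficient lines against both the ATM-deficient and the IkB-DN lines were found for 13 probe sets. Of the 149 probe sets called higher in Artemis-deficient than in RAG-2-deficient lines, 19 were also higher than without ATM, 29 were higher than with IkB-DN and 12 were both. By the representative probe set of each gene these were Nfkbie, Relb, Pim2 and Swap70, together with Cyba, Sdhaf1 and Slc20a1, which were chosen after their values were seen. Other probe sets added Nfkb2 (3.17 against the ATM-deficient and 3.26 against the IkB-DN lines), Limd2 and Shisa5, chosen in the same way. Cyba, a subunit of the NADPH oxidase, was higher by 1.80 than in RAG-2-deficient, by 1.90 ± 0.24 than in ATM-deficient and by 1.49 ± 0.21 than in IkB-DN lines. The phosphate transporter gene Slc20a1 was higher by 2.17, 1.497 ± 0.234 and 1.672 ± 0.209 and Sdhaf1, an assembly factor of succinate dehydrogenase, by 1.23, 1.26 ± 0.15 and 1.15 ± 0.13. The 2 comparisons share the Artemis-deficient samples, which in simulated data gives a correlation of 0.445 between changes; the measured correlation was 0.0851. No number of shared calls expected from the sharing was computed, so the 13 were not tested against chance. None of the 100 probe sets lower than in RAG-2-deficient lines was also called lower than in both other groups.

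The difference between the ATM-deficient and the IkB-DN lines was tested as well. Immediate early genes were lower in the ATM-deficient lines: Jun fell by 3.16 ± 0.48 (SE, n = 2 and 3, adjusted p = 0.00521), Hspa1b by 1.75 ± 0.40, Ier2 by 0.73 ± 0.17 and Zfp36 by 0.71 ± 0.19, 4 of 12, while the list as a set was not called (adjusted p = 0.134). Among 23 NF-kB targets Bcl2l1 rose (0.75 ± 0.15) and Ltb and Icam1 fell by 4.59 ± 0.81 and 0.58 ± 0.16, without a call of the list (adjusted p = 0.700). Rag1 fell by 2.09 ± 0.42, and the repair genes Parp1, Prkdc and Poll fell by 2.08 ± 0.43, 0.78 ± 0.21 and 0.76 ± 0.19. Tnfsf10 (-1.91 ± 0.24), Lyz2 (-3.00 ± 0.49), Rnase4 (-4.56 ± 0.54), Retreg1 (-5.84 ± 0.92) and H2-Oa (-3.04 ± 0.56) fell too, and Prdm1 (3.90 ± 0.93), H2-K1 (0.27 ± 0.07) and Pfn2 (5.36 ± 0.77) rose. Of 25 p53 targets Gadd45a rose (2.00 ± 0.50) and Ddb2 fell (-1.24 ± 0.29), Cd44 (-3.17 ± 0.80) fell with Icam1 of 19 homing genes, Il18 (-1.33 ± 0.36) fell of 16 cytokine genes and Herpud1 (0.33 ± 0.08) rose of 15 unfolded protein response genes. The 4 sets were not called (adjusted p between 0.566 and 0.993). The 12 largest rises also held Sptbn1, Tceal9, Acp5, Sspn, Slco1a5, Cacna1e, Eng, Lrrn3, Vsir and Cpeb2 (4.09 to 6.73, SE 0.57 to 1.51), with n = 2 and 2 for Tceal9, Acp5 and Sspn. The 12 largest falls also held Garem1, A630023P12Rik, Rnf130, Aim2, Endou, Ankrd33b and Igsf5 (-7.03 to -4.30, SE 0.62 to 1.20). Xist rose by 7.22 ± 1.61 and the Y-linked Eif2s3y (-7.24 ± 1.78) and Kdm5d (-4.82 ± 1.24) fell. All 23 G2 and M phase genes were positive (median 2.08, adjusted p = 7.86e-07, and adjusted p = 0.945 with an estimated correlation), with 0 called and 12 at an unadjusted p below 0.05; Birc5 was at 3.38 ± 1.17 and Kif20a at 2.40 ± 0.80. Of 21631 probe sets, 1431 were called, 667 higher and 764 lower. The count was 359 and 438 without Artemis- and ATM-deficient replicate 1 and 2 and 407, 343 and 666 without IkB-DN replicate 1, 2 and 3. Jun, Tnfsf10, Pfn2, Retreg1, Rnase4, Vsir and Igsf5, of 44 called genes named, stayed called whichever sample was left out.

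Bone marrow pre-B cells from Artemis-deficient mice were compared with those from RAG-1-deficient mice, as unrepaired breaks against none in primary cells. Genes of antigen presentation rose in the Artemis-deficient cells, 6 of 14, with 9 rises when adjusted over the list alone: H2-Eb1 (2.79 ± 0.42, SE, n = 2 and 2, adjusted p = 0.0280), H2-Aa (2.13 ± 0.38) and H2-DMa (1.74 ± 0.28) of the class II pathway, and the costimulatory receptor Cd40 (1.80 ± 0.26) were among them, while H2-Ob fell by 1.54 ± 0.24. The NF-kB targets Nfkbie (1.64 ± 0.27, adjusted p = 0.0346), Tnfaip3 (1.20 ± 0.19), Icam1 (1.18 ± 0.21) and Cd40 were among 6 of 29 that rose, 10 when adjusted over the list alone. Interferon response genes rose, 3 of 24, with 10 when adjusted over the list alone: Mx1 (1.71 ± 0.25), Bst2 (2.51 ± 0.39) and Trim30a (1.13 ± 0.22). All 3 lists were higher as sets, with adjusted p of 2.10e-06, 3.18e-06 and 1.84e-07. With an estimated correlation none was (adjusted p = 0.405, 0.405 and 0.461). Relative to the mean of the 4 marrow samples, the mean interferon response level was -0.0015 and 0.72 in the Artemis-deficient replicates 1 and 2, of which replicate 2 stood apart, and -0.49 and -0.23 in the RAG-1-deficient ones. For antigen presentation it was 0.40 and 0.67 against -0.86 and -0.21, with RAG-1-deficient replicate 1 apart, and for NF-kB targets 0.30 and 0.32 against -0.42 and -0.20. Of 16 cytokine genes Tnfrsf13b rose (0.80 ± 0.16), with 3 rises when adjusted over the list alone (adjusted p of the list = 0.0191, and adjusted p = 0.461 with an estimated correlation).

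Markers of other cell types moved with the same samples. Dendritic cell markers rose, 5 of 7, with 6 when adjusted over the list alone (median 1.48, adjusted p = 4.83e-08, and adjusted p = 0.405 with an estimated correlation): Siglech (2.58 ± 0.38), Bst2, Flt3 (1.48 ± 0.20), Tcf4 (1.20 ± 0.19) and Itgax (1.04), the last chosen after its values were seen. The myeloid genes Lyz2 (1.05 ± 0.16) and Ctsg (1.54 ± 0.28) rose of 17 neutrophil and monocyte markers, of which 13 rose when adjusted over the list alone (median 0.82, adjusted p = 7.52e-11, and adjusted p = 0.405 with an estimated correlation). Cd8b1 (3.68 ± 0.52) rose of 11 T and NK cell markers, with 6 when adjusted over the list alone (median 0.71, adjusted p = 2.97e-05, and adjusted p = 0.405 with an estimated correlation). Erythroid markers had 0 calls of 9 and 6 falls at an unadjusted p below 0.05, with Klf1 at -0.74 ± 0.18 (adjusted p = 0.0875) and Slc4a1 at -0.66 ± 0.18 (adjusted p = 0.109); 4 fell when adjusted over the list alone (median -0.66, adjusted p = 0.00235, and adjusted p = 0.461 with an estimated correlation). RAG-1-deficient replicate 1 stood apart on the first 3 of these lists. The mean level of dendritic cell markers was -1.22 and -0.40 in RAG-1-deficient replicates 1 and 2 and 0.64 and 0.98 in the Artemis-deficient ones, that of neutrophil and monocyte markers -0.67 and -0.19 against 0.50 and 0.36, and that of T and NK cell markers -0.63 and -0.19 against 0.33 and 0.49. Erythroid markers were at 0.31 and 0.15 against -0.43 and -0.03, with Artemis-deficient replicate 1 apart. Without RAG-1-deficient replicate 1 limma called 0 probe sets in marrow, with 1757 at an unadjusted p below 0.05. The largest rises included the lectin receptors Cd209d (4.31 ± 0.69) and Clec10a (3.39 ± 0.52) and the checkpoint receptor Lag3 (3.08 ± 0.52), with Ptprf, Eldr, D13Ertd608e, Pacsin1, Smim5 and Ccdc162 (2.59 to 3.89, SE 0.33 to 0.73). The largest falls included those of Ret, Col27a1, Ms4a6c, Smtnl2, Asb2, Endou, Gfra2, Dusp18, Bcat1 and 1700016A09Rik (-2.94 to -1.90, SE 0.20 to 0.48), with another probe set of Ms4a6c at 0.81.

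**Figure D3:**
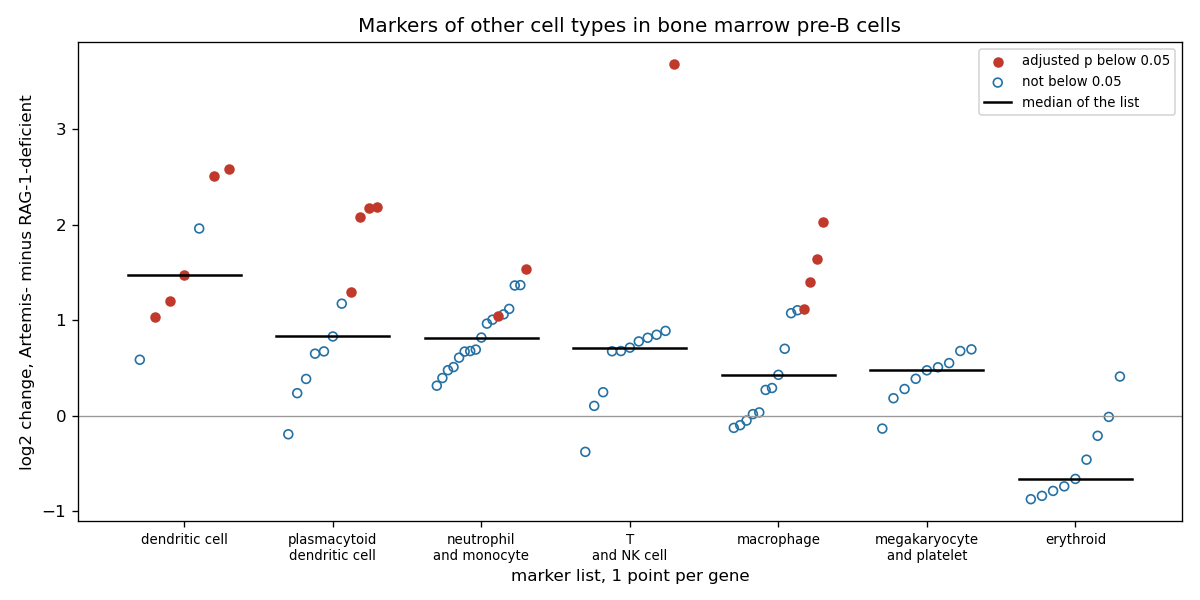
Each point is the log2 change of 1 marker gene in Artemis-deficient minus RAG-1-deficient bone marrow pre-B cells, grouped by list, with called genes filled and the median of each list as a bar. The dendritic cell list has a median of 1.48 and the erythroid list of -0.66; the plasmacytoid dendritic cell, macrophage and megakaryocyte lists were written after the data had been seen.

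Of 31 B lineage genes 2 fell and 1 rose in the Artemis-deficient marrow cells. Rag1 fell by 2.00 ± 0.22 (SE, n = 2 and 2, adjusted p = 0.0228) and the surrogate light chain gene Vpreb1 by 1.33 ± 0.23. The myeloid and B lineage factor Irf8 rose by 1.41 ± 0.19, and Rag2 was at -1.49 ± 0.32 (adjusted p = 0.0618). Rag1 is the gene targeted in the control mice, so its difference cannot be told apart from an effect of that targeting. Adjusted over the list alone, 3 rose and 16 fell (median -0.64, adjusted p = 2.31e-07, and adjusted p = 0.405 with an estimated correlation). Unfolded protein response genes fell, 2 of 14 and 11 when adjusted over the list alone (median -0.60, adjusted p = 4.02e-08, and adjusted p = 0.405 with an estimated correlation): Sdf2l1 by 1.73 ± 0.30 and Ddit3 by 1.26 ± 0.22. The mean level of that list was -0.60 and -0.23 in the Artemis-deficient and 0.61 and 0.22 in the RAG-1-deficient replicates, and that of the S phase list -0.09 and -0.20 against 0.30 and -0.01. Derl3, which acts in the degradation of misfolded proteins, fell by 3.53 ± 0.23 (adjusted p = 0.00609). Plasma cell markers had 0 calls of 6 and 4 falls at an unadjusted p below 0.05, with Irf4 at -0.81 ± 0.20 and Mzb1 at -0.66 ± 0.17 (adjusted p of the list = 0.000643, and adjusted p = 0.405 with an estimated correlation). S phase genes (24), G2 and M phase genes (23) and homologous recombination genes (12) had 0 calls, with 6, 4 and 3 falls at an unadjusted p below 0.05 and adjusted p of 0.000125, 2.03e-05 and 0.00259 as sets. With an estimated correlation they had an adjusted p = 0.461, 0.461 and 0.405.

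The p53 targets Zmat3 (2.61 ± 0.34) and Pmaip1 (1.51 ± 0.27), the latter encoding the apoptosis inducer NOXA, rose of 24, without a call of the list (adjusted p = 0.708), and the apoptosis gene Bmf fell by 1.79 ± 0.21. The end joining genes Xrcc6, encoding Ku70, and Lig4 fell by 1.21 ± 0.19 and 1.13 ± 0.16, 2 of 22 (adjusted p = 0.115). Among 21 homing genes the integrin Itgal (1.22 ± 0.17) and Cd44 (0.93 ± 0.17) rose with Icam1 and the egress receptor S1pr1 fell by 1.18 ± 0.21 (adjusted p = 0.00146, and adjusted p = 0.405 with an estimated correlation). Of 19473 probe sets, 489 were called, 346 higher and 143 lower. The count was 1175 and 1245 without Artemis-deficient replicate 1 and 2 and 0 (by limma, with 1757 at an unadjusted p below 0.05) and 73 without RAG-1-deficient replicate 1 and 2, and without an intensity trend in the variance model it was 14. None of the 56 called genes named stayed called whichever sample was left out.

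The changes in lines and in marrow cells, measured on separate arrays, were set against each other. Of 17575 probe sets tested in both, 8 were called higher with Artemis deficiency in both, against 1.36 for independent calls (two-sided Fisher's exact p = 6.81e-05), and 0 were called lower in both, against 0.617. With 1 probe set per gene, 6 were called higher in both, against 0.797 (two-sided Fisher's exact p = 0.000136). The test takes genes as independent, and the marrow calls depended on RAG-1-deficient replicate 1. Markers of other cell types rose in the same marrow comparison. The 8 probe sets named Nfkbie, Tnfaip3 (2 probe sets), Icam1 and Nfkbid of the NF-kB pathway, its upstream kinase Map3k8, the cyclin gene Ccnd1 and Shisa5; those outside the naming rule in marrow were chosen after their values were seen. Ccnd1 was higher by 1.83 ± 0.26 in lines and by 2.04 ± 0.33 in marrow, Map3k8 by 1.58 ± 0.31 in each, and Nfkbid by 2.28 ± 0.36 and 1.01 ± 0.18. Lifr was called in opposite directions, -2.71 ± 0.40 in lines and 1.71 ± 0.25 in marrow. Of the 118 probe sets called higher in lines, 79 had a positive change in marrow (66.9%, camera p = 1.36e-05), but with an estimated correlation the p was 0.159.

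The 100 genes highest in Artemis-deficient marrow, chosen independently of the lines, were tested in the line comparisons, where 49 of them were expressed. The camera p values of these sets were not adjusted over the sets or the comparisons. A set is called here at an unadjusted p below 0.05. They were higher in Artemis-deficient than in RAG-2-deficient lines (median 0.20, camera p = 0.00179, and p = 0.0836 with an estimated correlation). They were also higher in Artemis-deficient than in ATM-deficient lines (median 0.38, p = 0.000265, and p = 0.0492 with an estimated correlation). Between Artemis-deficient and IkB-DN lines the set was not called (median -0.15, 20 of 49 positive). Against RAG-2-deficient lines the medians were 0.42 in IkB-DN, 0.18 in wild type and -0.12 in ATM-deficient lines; the set was called in the first 2 with the preset correlation and in none with an estimated one. The 100 lowest genes, of which 92 were expressed, were lower in Artemis-deficient than in RAG-2-deficient lines (camera p = 0.0222, and p = 0.157 with an estimated correlation). They were also lower in wild type than in RAG-2-deficient lines (camera p = 0.000157, and p = 0.0309 with an estimated correlation).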

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

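The tests of the erythroid list, of the likeness of Artemis-deficient replicate 3 to the IkB-DN lines and of that replicate alone were chosen only after the result was seen. So were the second marker lists. For the tests of the erythroid list and of replicate 3, what each would have to show was also written down after the result was seen. Their outcomes are therefore not predictions that were met. For the second marker lists it was written down before their values were read. The check of the C1q genes is an exception, added for macrophages alone after the median of their list was seen.

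The change with Artemis deficiency differed between lines and bone marrow cells for 166 of 22503 probe sets, 62 with a positive and 104 with a negative difference of lines minus marrow, by a test of the difference itself in a limma fit of 18 samples. An unadjusted p below 0.05 was reached by 2988. For Lifr the difference was -4.33 ± 0.56 (SE, adjusted p = 0.00406), with -2.59 in the lines and 1.73 in the marrow, and it was the only one of the 67 genes called in both comparisons on their own. The controls are RAG-2-deficient in one set and RAG-1-deficient in the other, and the lines were kept in STI571, so origin, control and treatment cannot be separated here.

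Regrouping the samples of the 5 comparisons of 3 with 3 lines gives 10 splits each, too few for a share under 0.05; in each, 1 split reached the real count, the real one. Artemis-deficient against RAG-2-deficient lines had 249 calls, and the highest other split had 6. The counts were 172 and 11 for wild type against RAG-2-deficient, 2134 and 0 for IkB-DN against RAG-2-deficient, 439 and 0 for Artemis-deficient against IkB-DN, and 110 and 15 for Artemis-deficient against wild type lines.

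Markers of dendritic cells, neutrophils and monocytes were higher in Artemis-deficient than in RAG-1-deficient bone marrow cells, which the labels call purified; no gate is given in the sources used here. A lower share of pre-B cells with every other cell type raised alike would raise erythroid markers too. Against that, the 9 erythroid markers had a median of -0.662 and the 7 dendritic cell markers one of 1.48 (exact permutation p = 8.74e-05). This p takes genes as independent units and does not measure the spread between mice. A lower share of pre-B cells with only some other cell types raised is not excluded and stays open. A second list of 11 plasmacytoid dendritic cell markers had a median of 0.829, above 100% of 10000 random lists matched on level. Of these markers 9 were also tested in the lines, so they are not particular to such cells, and 2 were held by a first list. Random lists hold unrelated genes and vary less than markers that move together. T and NK cell (99.98%) and megakaryocyte markers (99.89%) also lay above nearly all random lists. A higher share of plasmacytoid cells may be part of the pattern, but this measure does not single it out. The 15 macrophage markers had a median of 0.428, above 99.99% of random lists, which met the condition written beforehand. The 3 C1q genes, abundant in macrophages, had a median of -0.0513. That check was added after the median of the list was seen and was made for macrophages alone, so macrophages stay open. Expression of these genes by pre-B cells with unrepaired breaks, the biological explanation, stays open as well, since only 2 of the 7 called members were detected in the lines (median -0.194).

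More probe sets were called for the IkB-DN lines than for the other lines. Their replicates varied least (median SD 0.159, against 0.170 to 0.263 in the other line groups), and they may not be separate lines. The deviation of Artemis-deficient replicate 3 from its group correlated with IkB-DN minus wild type at 0.319, against -0.352 and -0.0326 for replicates 1 and 2, so the IkB-DN lines may share their origin with Artemis-deficient replicate 3. Line origin as the source of the lower NF-kB genes cannot be told apart from the block of NF-kB: with replicate 3 alone, 1 sample in that arm, 3 of the 6 called genes stayed called (Relb 2.58 ± 0.27, SE, Nfkbie 2.32 ± 0.25, Birc3 1.64 ± 0.21) and all 6 kept their sign. The lost calls came with wider errors and not with smaller changes, so they do not speak for line origin: Pim2 went from 3.42 ± 0.55 to 4.06 ± 0.79, Nfkbia from 1.17 ± 0.18 to 1.26 ± 0.28 and Nfkb2 from 0.82 ± 0.17 to 0.99 ± 0.20.

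NF-kB genes were higher in Artemis-deficient than in Artemis- and ATM-deficient lines. A difference in cycling between the cultures as the whole cause is argued against by a fit with the G2 and M phase score as a covariate, in which 4 of 4 genes stayed called and their median went from 3.06 to 3.25 (median SE 0.411). With quantile normalization 4 of 4 stayed called, with a median of 3.06. The line arrays already had nearly equal median signals (26.8 to 27.7), so this step could hardly move changes of that size. It cannot decide whether the original summary and scaling of the arrays play a part. Loss of ATM, the biological explanation that the design names, stays open beside differences between lines that were not tested.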

How the results depend on the processing

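Alternatives chosen only after the result was seen were the G2 and M phase score as a covariate, replicate 3 alone, the log values as deposited and empty cells at a signal of 0. No paired analysis was possible because replicate numbers follow the order of the samples and pair nothing across groups.

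Of 378 named gene results 344 were called. Over the settings other than left-out samples and other probe sets, the called results kept their call in 3941 values and lost it in 670, and with a sample left out in 896 and 880; none of these changed sign. The largest shares were lost with replicate 3 alone (28 of 37) and with the marrow fitted together with the lines (34 of 56), then with only the 2 compared groups in the fit (115 of 288), the G2 and M phase covariate (88 of 288) and no intensity trend (101 of 344). The smallest were lost with quantile normalization (10 of 344), empty cells at a signal of 0 (12 of 344) and a pseudocount at the median signal (15 of 344). Other probe sets of called genes kept the call in 110 values, lost it in 91 and reversed the sign in 9. Ctse (-1.509) and Xaf1 (-2.126) reversed in Artemis-deficient against RAG-2-deficient lines. Xaf1 also reversed in ATM-deficient against RAG-2-deficient lines (-2.119) and in Artemis-deficient against wild type lines (-1.325). Chd1 (0.4112) reversed in Artemis-deficient against ATM-deficient lines, and Ctse (-1.147) and Trim34a (0.9082) in IkB-DN against RAG-2-deficient lines. The others were Add3 (-0.02752) in Artemis-deficient against IkB-DN lines and Ms4a6c (0.8115) in bone marrow. The cause of these reversals was not tested. Among uncalled results, leaving out RAG-2-deficient replicate 1 reversed Rag1 in Artemis-deficient (-0.06061, highest 0.40) and wild type lines (-0.1065, highest 0.34) and Rag2 in wild type lines (-0.3271, highest 1.52).

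With 1 probe set per gene the counts were 88 and 58 for Artemis-deficient and wild type against RAG-2-deficient lines, 48 for ATM-deficient and 1026 for IkB-DN lines, 28, 266 and 56 for Artemis-deficient against ATM-deficient, IkB-DN and wild type lines, and 680 for ATM-deficient against IkB-DN lines. With only the 2 groups in the fit they were in that order 103, 29, 76, 3100, 22, 821, 6 and 3156. Array weights gave 113 for wild type and 4144 for IkB-DN against RAG-2-deficient lines, and 2446 and 2914 for Artemis-deficient and ATM-deficient against IkB-DN lines. A 2-fold threshold gave 1149, 270 and 866 in the 3 comparisons with IkB-DN lines, which it can only lower. A stricter filter gave 84 for ATM-deficient against RAG-2-deficient lines, replicate 3 alone 58 against IkB-DN lines and the covariate 306 for ATM-deficient against IkB-DN lines. Bone marrow had 758 calls without a filter and 14 without an intensity trend. Probe sets higher in both lines and marrow were 13 with quantile normalization and 15 without a filter. Except for the 2-fold threshold, the cause of these moves was not tested. The counts of the 2-group fits fell in every comparison without IkB-DN lines and rose in every comparison with them. The IkB-DN replicates varied least (median SD 0.159), and the fit of all line groups shares its spread with them.

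Leaving out each sample gave 93 to 199 calls for Artemis-deficient, 69 to 302 for wild type, 46 to 133 for ATM-deficient and 840 to 1454 for IkB-DN against RAG-2-deficient lines. It gave 29 to 66, 59 to 1065 and 45 to 180 for Artemis-deficient against ATM-deficient, IkB-DN and wild type lines, 343 to 666 for ATM-deficient against IkB-DN lines, and 0 to 1245 in bone marrow, where a lone sample is assumed to vary like the other group; limma's 0 came without RAG-1-deficient replicate 1, with 1757 at an unadjusted p below 0.05.

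With an estimated correlation 5 of the 50 called list tests stayed called, against 44 with quantile normalization and 50 with a pseudocount of 1. The NF-kB list was then not called in Artemis-deficient against IkB-DN lines (0.1, with 7.92e-06 to 0.1 over its alternatives) or in bone marrow (0.405, with 2.11e-06 to 0.405). The bone marrow genes in Artemis-deficient against IkB-DN lines, uncalled, changed direction with a stricter filter (0.889, with 0.27 to 0.889 over the alternatives); the cause was not tested. Low signals limit the comparisons, with empty cells concentrated there.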

Other observations

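The second marker lists were chosen only after the result was seen. In bone marrow, 3 mast cell and basophil markers had a median change of 0.258, above 82.2% of random lists, and 9 megakaryocyte and platelet markers one of 0.475, above 99.9%; limma called 0 genes of either list, with 0 and 2 at an unadjusted p below 0.05, the 2 being Vwf (0.68 ± 0.25) and Itga2b (0.55 ± 0.22), chosen after their values were seen.

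Xist followed the line groups except the Artemis-deficient one. It was high in all wild type and ATM-deficient lines and low in all RAG-2-deficient and IkB-DN lines, while the Artemis-deficient lines were mixed. Between a group with high and a group with low Xist, sex-linked differences and genotype cannot be separated. Kdm5d was 7.93, 8.12 and 7.96 in the RAG-2-deficient lines, 8.18 and 7.88 in Artemis-deficient replicates 2 and 3, and 2.62 in Artemis-deficient replicate 1. Eif2s3y was 3.12 in RAG-2-deficient replicate 3, against 10.41 and 10.12 in the other RAG-2-deficient lines.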
